A study of Mus musculus with 3 samples.

How the data were processed

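Poly(A)-selected RNA of sorted P14 CD8+ T cells was sequenced as paired ends, per the labels' protocols. The submitters' processing notes name the genome build mm9 and the tools CASAVA 1.8, TopHat, Cufflinks and edgeR, without versions for the last 3 and without saying which tool made which value. The read length, the annotation release and any filter were not given in the sources used here. The deposited values are FPKM, read numbers scaled to transcript length and library total, with 1 value for each of 95495 annotated transcripts of 37310 gene identifiers in each of 6 libraries, and each library was deposited separately. The labels give 1 sample for each stage with 2 files, which were taken as replicate libraries.

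The deposited FPKM values were checked for whole reads. For all expressed transcripts that could be checked, FPKM multiplied by a transcript length and a library total gave a whole number within 0.01 reads (100% of them). The recovered length equalled the length in a reference annotation for 96.6% of expressed transcripts with a known length. That annotation (GENCODE vM21) belongs to a later genome build, shares 41216 transcript identifiers (43.2%) with the files, and was used only for lengths and shared sequence, so that no genomic position is given. The recovered totals were 106837575 and 96020385 for naive, 119911666 and 124137531 for effector, and 71963070 and 65557922 for memory replicates 1 and 2. These totals scale the values. The reads recovered for all transcripts summed to slightly less, from 65373675 in memory replicate 2 to 123794396 in effector replicate 2, and these sums count a read once for each transcript it overlaps.

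Each gene was represented by the transcript with the most reads over the 6 libraries, and values of transcripts were not summed because a shared read would then be counted more than once. Gene symbols were those of the files, where 343 symbols had more than 1 gene identifier. As a measure of reads that could belong to several genes, the share of a gene's 50-base stretches that also occurred in another gene's transcripts was computed for 10967 of the 11977 tested genes (91.6%). Of the named genes, Ifng, Ctla2a, Mid1, Klrc1, Stat4, Cdc20, Cox5b, Rps19, Rplp0, Uhrf1, Lyz2, Klrb1c and Trbc2 had a share of 10% to 50%. Higher shares are given beside the gene. Some named genes had no computed share, among them Tcf7, Gsn, Lilrb4, Oas1a, Ppp1r15a, Hdac7 and H2-Ab1. Values of genes with a high share are uncertain, since the handling of reads with several matches was not given in the sources used here. Whether counting used the strand was not given either, so overlapping and antisense genes could not be told apart.

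Genes with at least 1 FPKM in at least 2 libraries were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with all 3 stages in 1 fit and a mean-variance trend. The fit had 3 residual and 3.17 prior degrees of freedom. Adjusted p-values are Benjamini-Hochberg values over the tested genes of a comparison, and a gene was called at an adjusted p under 0.05. The design had assumed a gene-level unit, and the transcript values were used as described instead. Because FPKM are not counts, no count model was the primary test, and limma-voom on the recovered reads was an alternative.

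The lists held 423 genes, of which 421 were found and 365 tested, in 20 lists of CD8 T cell biology and 7 of other cell types. Lists of at least 3 tested genes were tested with camera of limma at a preset correlation of 0.01, with an estimated correlation, and with fry, which tests whether a list's genes move, on balance, 1 way and does not compare them with other genes. The other-cell lists cover B cells, monocytes, macrophages and neutrophils, dendritic cells, CD4 T cells, NK cells, erythroid cells and stroma of lymph node and spleen. The lists, the test, the grouping and the rule for named genes were fixed before the data were examined.

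The rule named, in each comparison, the 8 genes with the largest rise and the 8 with the largest fall among those called, with both libraries of a stage above both of the other and a mean of at least 5 FPKM in the higher stage. It left out of these names, but not of the counts, predicted genes and some clone names, small RNAs, antigen receptor segments, symbols with several identifiers, histone clusters, mitochondrial and Y-linked genes and Xist. The clone-named genes AC073553.2, AC124005.1 and AL929120.1 did not match the name patterns of the rule and stayed in. In each list it named up to 2 called genes with the largest rise and up to 2 with the largest fall, and it named the sort markers as a check of the labels. Values of some genes that the rule names are not reported here.

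The procedure was tested on simulated data with 50 genes changed at each fold size. At 1.5-fold it recovered 76% of changed genes for effector against naive (11306 genes), 84% for memory against naive (11310 genes) and 86% for memory against effector (11294 genes), and at 2-fold 94%, 92% and 88%. At 4-fold it recovered 96% in each, and at 8-fold 94%, 98% and 96%. Of the calls in these simulations 6.74%, 9.76% and 8.04% were false, each more than the threshold of 0.05 allows for. Few genes were changed, in 1 stage, and all genes were given the same spread between replicates. Most tested genes were called in the data, so these rates may not carry over.

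Alternatives planned before the data were seen were pseudocounts of 0.1 and 5, no filter and a minimum of 5 FPKM, upper-quartile scaling and quantile normalization, fits without the trend, with a robust prior or with only the stages compared, an adjusted p under 0.01 or a 2-fold minimum, a block for the replicate number, and each library left out. Alternatives chosen after seeing the data were the mean over transcripts, the transcript with the highest mean FPKM, limma-voom, a split of the naive libraries between the other stages, and restriction to genes or list members with under 10% shared 50-base stretches. Files were read with pandas 2.3.3 in Python 3.11.15, and figures were drawn with matplotlib 3.10.9.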

Results

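RNA sequencing was used to compare the transcriptomes of mouse CD8+ T cells at 3 stages of a response to lymphocytic choriomeningitis virus (LCMV). The cells carried the P14 transgenic T cell receptor, which recognises an LCMV glycoprotein peptide. Naive cells were sorted by surface markers, among them low to medium CD44, from the lymph nodes of uninfected P14 mice. For the other stages, 10000 naive P14 cells were transferred per recipient mouse and the recipients were infected with the Armstrong strain, which causes an acute infection. Effector cells were sorted on day 8 as KLRG1+ cells lacking the interleukin-7 receptor alpha chain, and memory cells from day 60 on as central memory cells. Each stage was deposited as 1 sample with 2 files, which were taken as 2 libraries and are called replicates 1 and 2. The labels do not say whether they came from separate animals, so the p-values measure only the spread between these libraries, which may be technical. Stage was confounded with infection, time, sort gate and, for naive cells, with the named tissue of origin. The reads recovered from the values summed to between 65373675 (memory replicate 2) and 123794396 (effector replicate 2) per library when a read was counted once in each transcript it overlapped. The transcripts used to represent the genes held 22435965 and 41746178 of these in the same libraries, and the median tested gene had 698 to 1173 reads per library. Counting noise was therefore lower in the effector than in the memory libraries.

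The 2 libraries of a stage lay close together. Across 11977 tested genes, Pearson's r of log2(FPKM + 1) was 0.987 to 0.995 between replicates and 0.814 to 0.910 between libraries of different stages (across genes, which are not independent replicates). The first principal component held 68.5% of the variance and separated effector from naive libraries, with memory libraries between them, and the second held 27.1% and separated memory from the other stages. Among genes with at least 1000 reads over both libraries of a stage, the median coefficient of variation between replicates was 3.48% to 3.94%. The replicates differed by more than counting noise, with a mean chi-square per gene of 6.46 to 11.6 on 1 degree of freedom, so no library was a copy of another. Below, levels are the mean FPKM ± SD over these 2 libraries of 1 sample (n = 2 libraries throughout), and fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes.

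The markers used for sorting followed the labels. Klrg1 was at 0.0641 ± 0.0344 FPKM in naive, 97.7 ± 5.72 in effector and 3.72 ± 0.642 in memory libraries. Il7r was at 33.8 ± 1.24, 1.17 ± 0.152 and 177.7 ± 0.0566 in the same order. Cd44 was at 0.454 ± 0.00569 in naive, 11.8 ± 0.522 in effector and 22.6 ± 0.448 in memory libraries. Ptprc, which encodes CD45, was at 113 ± 2.68, 143 ± 8.65 and 176 ± 2.5. Cd8a passed the test in no comparison, with 134 ± 3.84, 145 ± 1.48 and 138 ± 1.97, and the sign of its small log2 fold change turned under another scaling in each comparison. These genes chose the cells and are no finding.

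The comparison of effector with naive cells asked which genes changed between resting cells and the peak of the response. Most tested cytotoxic genes were higher in effector than in naive cells, and most naive and central memory surface genes were lower. Ccl5, a chemokine for T cells and monocytes, rose from 4.56 ± 0.22 to 3021 ± 77.9 FPKM (log2 fold change 9.09, SE 0.06, adjusted p = 2.76e-08). The granzyme genes Gzma (1.93 ± 0.17 to 842 ± 27.9, log2 fold change 8.17) and Gzmb (0.368 ± 0.0116 to 304 ± 27.3, log2 fold change 7.80) rose as well, both with the 2 effector libraries above the 2 naive ones. In all, 3540 of 11977 genes were higher and 4421 lower in effector cells at an adjusted p under 0.05 by limma, of which 926 and 937 differed by at least 2-fold. The median log2 fold change of all tested genes was -0.07.

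The other largest rises, chosen by the fixed rule, were of S100a4, Cx3cr1, Klrg1, S1pr5 and Itgax. S100a4, a calcium-binding protein of motile cells, rose from 0.68 ± 0.0747 to 409 ± 12.1 FPKM, although 56.4% of its 50-base stretches also occurred in another gene's transcripts. The fractalkine receptor gene Cx3cr1 rose from 0.0848 ± 0.0064 to 121 ± 2.04 and the sphingosine-1-phosphate receptor gene S1pr5 from 0.0616 ± 0.04 to 82.3 ± 6.66. Itgax, the integrin CD11c, rose from 0.0803 ± 0.00429 to 66.3 ± 1.87. The largest falls included those of Ccr7, Dapl1, Igfbp4, Nsg2, Itgae, Tcf7 and Ccr9. Ccr7, the receptor that guides T cells into lymph nodes, fell from 70.7 ± 7.99 to 1.03 ± 0.277 FPKM (log2 fold change -5.14, SE 0.11, adjusted p = 7.92e-07). Dapl1 went from 37.3 ± 0.624 to 0.106 ± 0.0463 and Igfbp4 from 36.0 ± 1.1 to 0.186 ± 0.0405. Tcf7, which encodes the transcription factor TCF-1, fell from 271 ± 1.8 to 13.5 ± 0.282. The chemokine receptor gene Ccr9 and the integrin gene Itgae, which encodes CD103, fell from 25.9 ± 0.161 and 27.8 ± 0.108 to 0.446 ± 0.035 and 0.276 ± 0.0309.

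**Figure D1:**
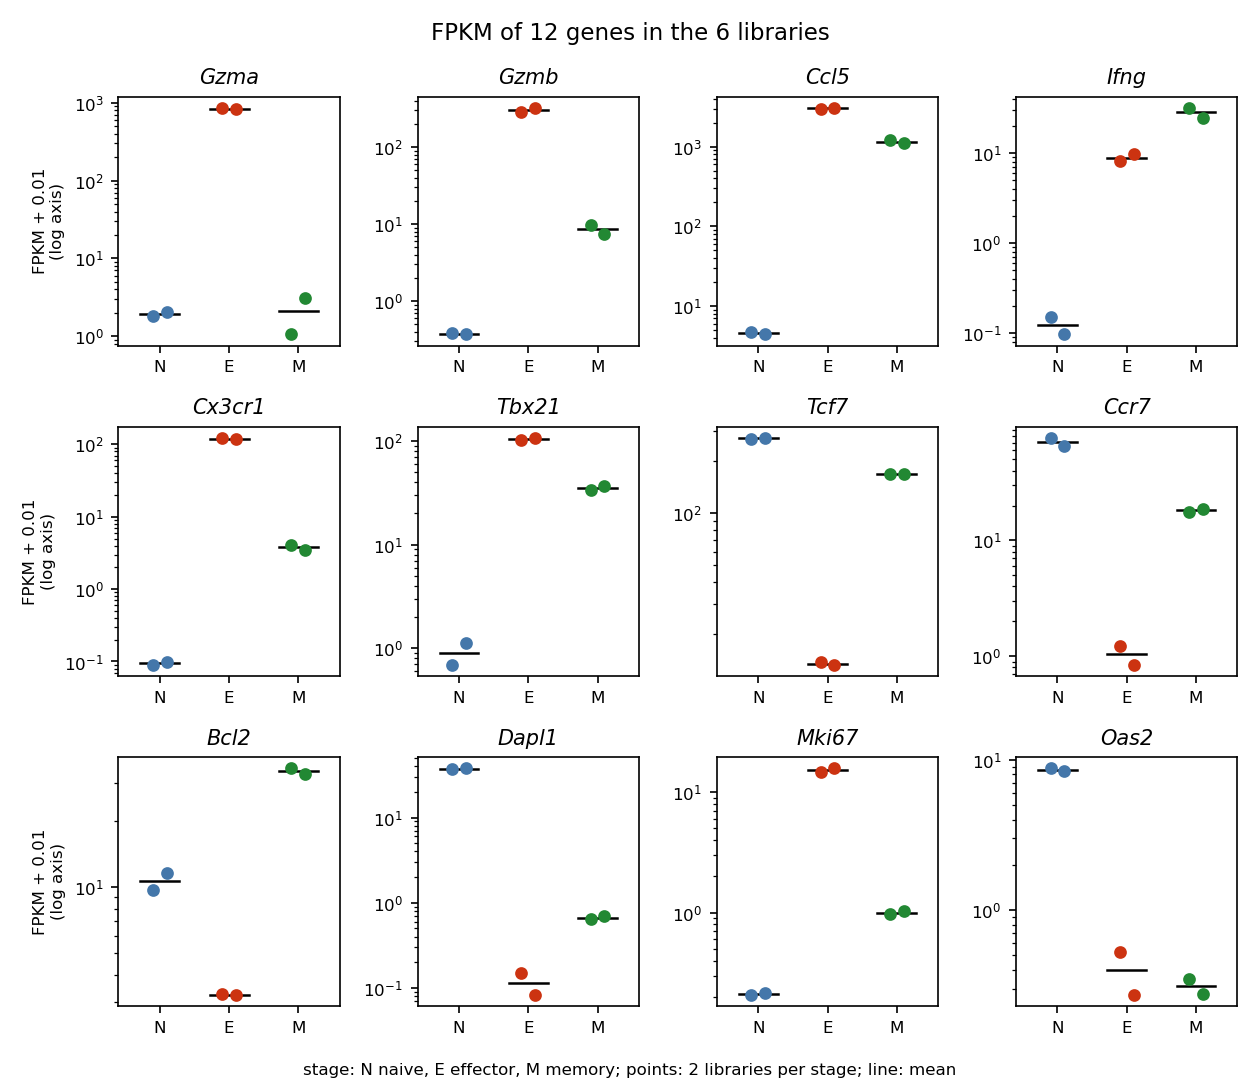
FPKM (log axis, with 0.01 added so that values of 0 can be drawn) of 12 genes in naive, effector and memory libraries, as 1 point per library with a line at the mean of the 2 libraries. Gzma stood at 842 in effector and 2.07 in memory libraries, whereas Ccl5 stood at 3021 and 1161, and Ccr7, Dapl1 and Tcf7 were lowest in effector libraries.

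Gene lists fixed before the data were examined were tested with camera at a preset correlation of 0.01, adjusted over 75 tests of 25 lists. Of these tests 44 passed at an adjusted p under 0.05, and with a correlation estimated from the 6 libraries 0 did, so each such p is given beside its list. That estimate rests on 3 residual degrees of freedom, so missing the threshold with it says little about a list. The passes in turn depend on the preset correlation. In effector against naive cells, 17 of 18 cytotoxic and secreted effector genes rose and 0 fell (17 and 0 adjusted over the list alone, adjusted p = 1.64e-09, and adjusted p = 0.194 with an estimated correlation). All 15 tested killer-lectin and effector surface receptor genes rose (15 adjusted over the list alone, adjusted p = 2.84e-10, and 0.194 as the adjusted p with an estimated correlation). All 14 effector-associated transcription factor genes rose too (14 adjusted over the list alone, adjusted p = 8.66e-08, and adjusted p = 0.194 with an estimated correlation). Among them Tbx21, which encodes T-bet, went from 0.899 ± 0.303 to 104 ± 3.51 FPKM and Bhlhe40 from 0.288 ± 0.0768 to 44.6 ± 2.37. Of 17 naive and central memory surface genes, 15 fell and 2 rose (15 and 2 adjusted over the list alone, adjusted p = 4.09e-06, and adjusted p = 0.194 with an estimated correlation). The 2 that rose were the chemokine receptor gene Cxcr3 (3.05 ± 0.883 to 30.8 ± 1.97) and the costimulatory receptor gene Cd28 (6.1 ± 0.32 to 10.9 ± 0.669).

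Naive and memory-associated transcription factor genes went both ways, with 10 of 18 lower and 5 higher in effector cells (10 and 5 adjusted over the list alone), and the list test missed the threshold (adjusted p = 0.0862). Id3 fell from 17.1 ± 1.06 to 0.903 ± 0.19 FPKM, whereas Runx1 (3.95 ± 0.422 to 8.34 ± 0.0226) and Eomes (5.51 ± 0.289 to 9.78 ± 1.14) rose. All 18 tested mitosis genes rose (18 adjusted over the list alone, adjusted p = 2.84e-10, and adjusted p = 0.194 with an estimated correlation), led by the proliferation marker Mki67, from 0.203 ± 0.00699 to 15.1 ± 0.823, and Ube2c, from 0.0813 ± 0.00829 to 12.2 ± 0.673. Of 20 DNA replication genes 16 rose and 0 fell (17 and 1 adjusted over the list alone, adjusted p = 3.35e-06, and adjusted p = 0.252 with an estimated correlation). Rrm2, a subunit of ribonucleotide reductase, went from 0.38 ± 0.00641 to 11.8 ± 1.36 and Chaf1a from 0.441 ± 0.0329 to 4.2 ± 0.423. Among 15 cell cycle inhibitor and quiescence genes 8 rose and 3 fell (8 and 3 adjusted over the list alone, adjusted p = 0.0424, which became 0.067 under quantile normalization, and adjusted p = 0.456 with an estimated correlation). Cdkn2c and Cdkn1a, which encode inhibitors of cyclin-dependent kinases, rose by 1.95 and 1.78 on the log2 scale, and Btg1 and Tsc1 fell by 0.98 and 0.49. Over members with under 10% of their 50-base stretches in another gene, a test chosen after seeing the data, the adjusted p of this list was 0.0595.

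Of 15 glycolysis genes 12 rose and 1 fell (12 and 1 adjusted over the list alone, adjusted p = 0.00098, and adjusted p = 0.216 with an estimated correlation). Hk2 went from 0.205 ± 0.00981 to 3.64 ± 0.0167 FPKM and Pfkp from 11.3 ± 0.265 to 37.6 ± 0.435. The gene that fell was Gapdh, whose 6.98 ± 0.182 FPKM in naive and 2.32 ± 0.155 in effector cells were low for a gene of central metabolism. It had 563 and 525 reads in the naive and 224 and 211 in the effector libraries. The median tested gene had 1028 and 948, and 1154 and 1173. The values of Gapdh, and so its fall, are therefore uncertain. Oxidative phosphorylation genes were higher in 11 and lower in 3 of 23 (11 and 3 adjusted over the list alone, adjusted p = 0.0143, which became 0.0553 under quantile normalization, and adjusted p = 0.216 with an estimated correlation). Cox5a rose by 0.86 and Cyc1 fell by 0.41 on the log2 scale. Of 16 fatty acid oxidation genes 8 rose and 2 fell (8 and 2 adjusted over the list alone), and the list test missed the threshold (adjusted p = 0.122). Etfb and Acadl rose by 1.42 and 1.07, and Lipa and Acadvl fell by 0.57 and 0.29. Of the 50-base stretches of Etfb, 67.3% occurred in another gene, so its value is uncertain. All 20 cytosolic ribosomal protein genes fell, with a median log2 fold change of -0.93 (20 adjusted over the list alone, adjusted p = 7.84e-07, and adjusted p = 0.204 with an estimated correlation). Rps19 went from 39.5 ± 0.212 to 14.9 ± 0.0809 and Rps16, with 59.4% shared stretches, from 135 ± 10.7 to 54.3 ± 0.011. Only 3 of the 20 had under 10% of their 50-base stretches in another gene, and all 3 fell.

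Among receptors and signalling genes, 11 of 15 chemokine receptor, integrin and homing genes rose and 1 fell (11 and 2 adjusted over the list alone, adjusted p = 0.000176, and adjusted p = 0.194 with an estimated correlation). Itgb1 rose from 5.14 ± 0.569 to 116 ± 4.09 FPKM, while Cd69 fell from 24.4 ± 2.78 to 4.84 ± 0.00408. Of 10 inhibitory receptor genes 7 rose and 2 fell (7 and 2 adjusted over the list alone, adjusted p = 0.0108, and adjusted p = 0.216 with an estimated correlation). Tigit went from 0.565 ± 0.18 to 26.5 ± 1.25 and Havcr2, which encodes TIM-3, from 0.018 ± 0.00377 to 9.52 ± 0.0651, whereas the transcription factor gene Tox and the receptor gene Btla fell by 1.62 and 1.21. Cytokine receptor and signalling genes rose in 9 and fell in 10 of 20 (9 and 10 adjusted over the list alone, adjusted p = 0.973), with a median of -0.19 while the camera direction was up. Both chains of the interleukin-18 receptor rose, Il18rap from 0.751 ± 0.432 to 87.4 ± 3.7 and Il18r1 from 4.25 ± 1.37 to 49.4 ± 1.15. Socs3 and Il4ra fell by 2.63 and 2.27.

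Interferon-stimulated genes were lower in effector than in naive cells for 15 of 21 members and higher for 2 (15 and 2 adjusted over the list alone, adjusted p = 0.00122, and adjusted p = 0.302 with an estimated correlation). Oas2 fell from 8.59 ± 0.254 to 0.39 ± 0.181 FPKM and Ifit1 from 7.64 ± 0.531 to 1.11 ± 0.193, while Oas1a and Ifit2 rose by 1.14 and 0.28. Apoptosis regulators rose in 8 and fell in 5 of 18 (8 and 5 adjusted over the list alone, adjusted p = 0.0734). Bcl2a1b, with 79.2% of its 50-base stretches in another gene, rose by 2.42, and the survival gene Bcl2 fell by 1.46 and Casp8 by 0.55. Chromatin regulators rose in 4 and fell in 10 of 22 (4 and 10 adjusted over the list alone, adjusted p = 0.309). Uhrf1, a partner of the maintenance DNA methyltransferase, rose from 1.13 ± 0.00607 to 5.01 ± 0.378 and the histone methyltransferase gene Ezh2 from 2.75 ± 0.21 to 8.18 ± 0.397, and Kdm6b and Hdac7 fell by 1.24 and 1.12. Of 14 immediate early genes 10 fell and 2 rose (11 and 2 adjusted over the list alone, adjusted p = 0.0166, and adjusted p = 0.525 with an estimated correlation). Ppp1r15a and Fos fell by 2.86 and 2.61, and Atf3 and Fosb rose by 1.62 and 0.48. CD8 T cell identity genes rose in 6 and fell in 4 of 12 (7 and 4 adjusted over the list alone, adjusted p = 0.338), with Cd2 up by 0.48, Cd8b1 up by 0.38, and Cd5 and Lat decreased by 0.50 and 0.27, and a median of 0.12 that turned to -0.01 under quantile normalization.

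Among the genes named in effector against naive cells, 5 of the smaller calls were lost when 1 library was left out. Fosb was lost without naive replicate 1 or 2 or effector replicate 1 (adjusted p = 0.051 to 0.102), and Ifit2 without naive replicate 1 or effector replicate 1 (adjusted p = 0.054 to 0.0683). Acadvl was lost without naive replicate 2 or effector replicate 2 (adjusted p = 0.0604 and 0.06). Lat was lost without any single library other than naive replicate 2 (adjusted p = 0.0507 to 0.174). Ctla4 was lost without naive replicate 2 or effector replicate 2 (adjusted p = 0.0545 and 0.0661).

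**Figure D2:**
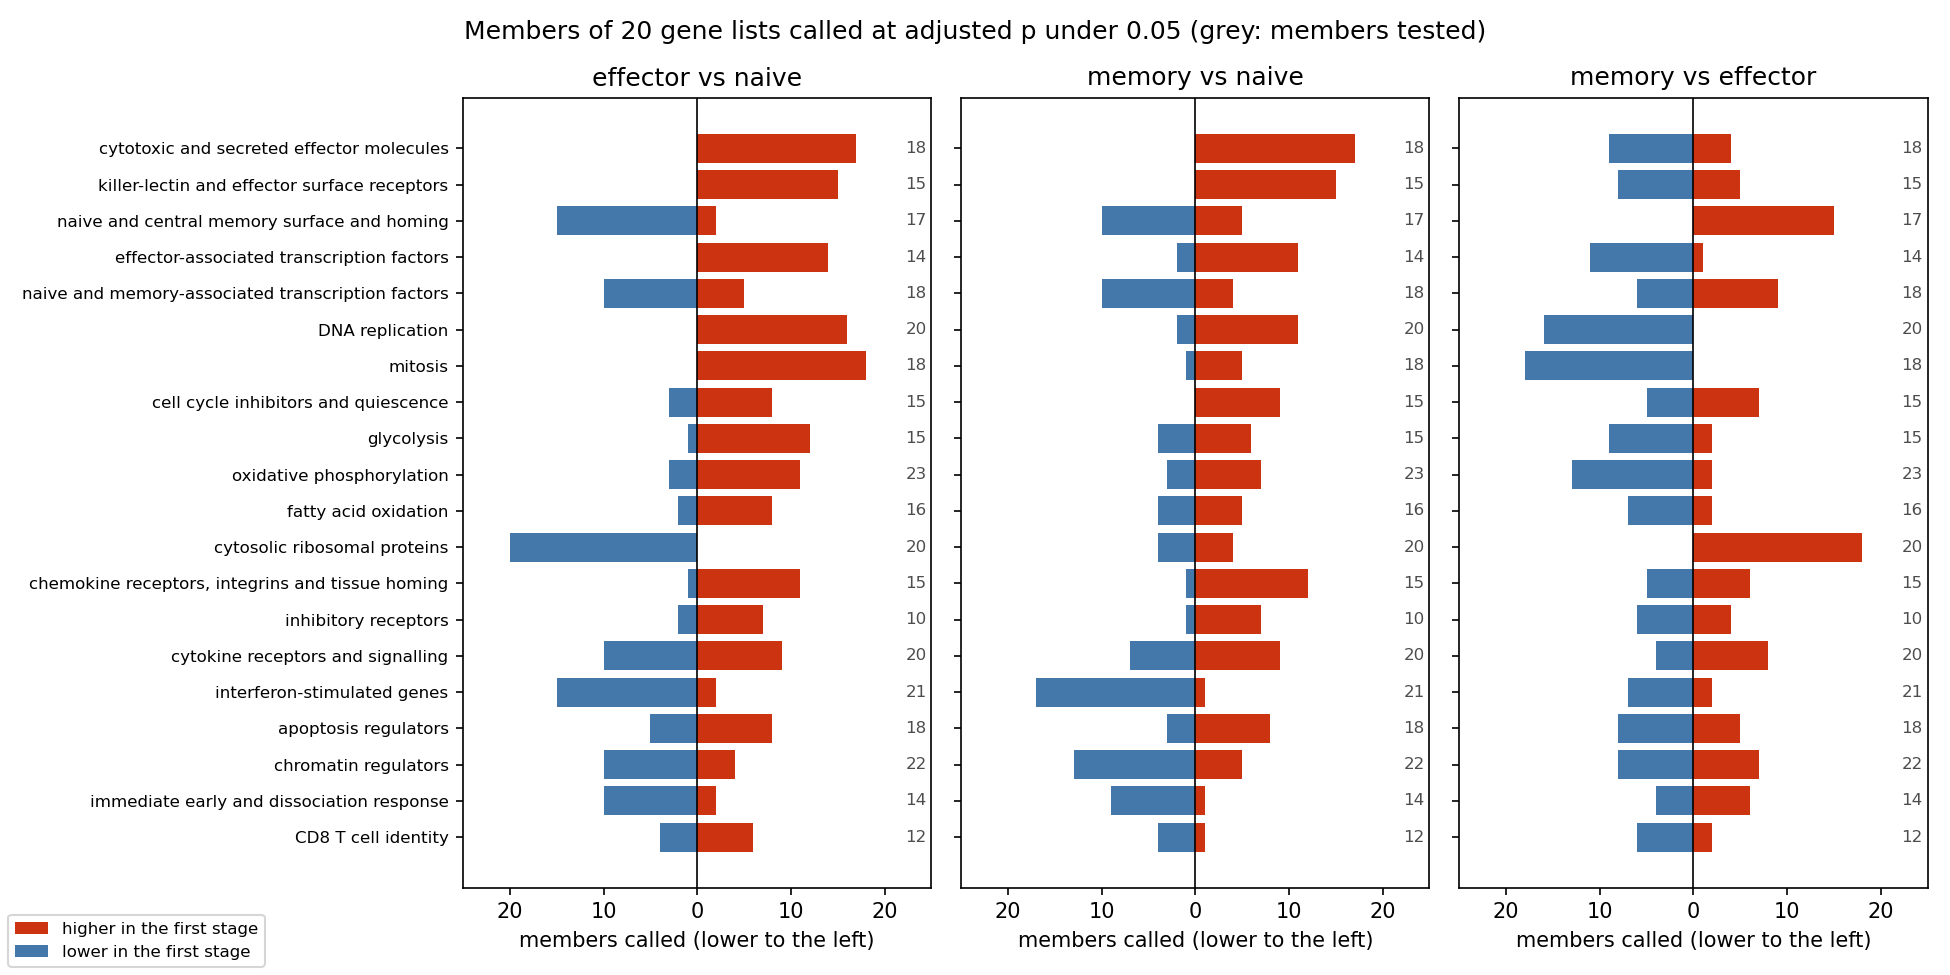
Number of members of each of 20 gene lists called higher (red, to the right) or lower (blue, to the left) in the first-named stage at an adjusted p under 0.05, with the members tested in grey at the right edge of each panel. Mitosis genes were higher in 18 of 18 in effector against naive cells, higher in 5 and lower in 1 of 18 in memory against naive cells, and lower in 18 of 18 in memory against effector cells, and ribosomal protein genes fell in 20 of 20 in effector cells.

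Markers of other cell types were also higher in the effector libraries, and this accompanied all of the gene groups above. All 8 tested monocyte, macrophage and neutrophil genes were called higher than in naive libraries (8 adjusted over the list alone, adjusted p = 0.000523, and adjusted p = 0.35 with an estimated correlation). S100a9 was at 56.6 and 23.1 FPKM in effector replicates 1 and 2, with 0.592 ± 0.582 in naive libraries, and Lyz2 at 31.0 and 22.2, with 0.172 ± 0.0926 in naive libraries. Of 6 tested B cell genes 5 were higher and 0 lower (5 adjusted over the list alone, adjusted p = 0.00243, and adjusted p = 0.252 with an estimated correlation), among them Cd74 at 80.3 ± 21.1 against 1.48 ± 0.334 and H2-Ab1 at 44.1 ± 11.8 against 0.439 ± 0.0988. Of 2 immunoglobulin genes outside this list, the light chain gene Igkc was also higher, at a mean of 228 against 1.68 in naive libraries. The heavy chain gene Ighm went the other way, from 128 ± 4.21 to 42.2 ± 1.73. All 3 tested erythroid genes were higher (3 adjusted over the list alone, adjusted p = 0.124), with Hbb-b1 at 12.2 and 3.08 and Hba-a1 at 4.81 and 1.44 in effector replicates 1 and 2. These had 65.8% and 67.5% shared stretches. Of 4 tested CD4 T cell genes 2 were higher and 1 lower (2 and 1 adjusted over the list alone, adjusted p = 0.479). Zbtb7b, a transcription factor of the CD4 lineage, went from 0.0495 ± 0.0218 to 16.3 ± 0.963, while Foxp3 fell by 0.48. Cd4 itself missed the FPKM minimum, at 0.547 and 0.604 in effector replicates 1 and 2 and a mean of 0.00954 in naive libraries. All 3 tested NK cell genes, of 7 fixed, were higher (3 adjusted over the list alone, adjusted p = 0.0235, and adjusted p = 0.231 with an estimated correlation), led by Klrb1c from 0.021 ± 0.00956 to 9.09 ± 0.253. The NK cell gene Ncr1 missed the FPKM minimum, at 0.0112 and 0.0485 in effector replicates 1 and 2. Of the stromal list only Pecam1 reached the FPKM minimum, at 14.4 ± 0.436 in naive and 4.76 ± 0.328 in effector libraries, and 0 of 9 dendritic cell genes did.

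The comparison of memory with naive cells asked what remained different after the response had ended. Memory cells had high levels of Ccl5 and of several effector genes, carried more Ifng than effector cells, and had Ccr7 at a level between those of effector and naive cells. Ccl5 was at 1161 ± 77.4 FPKM against 4.56 ± 0.22 in naive cells (log2 fold change 7.71, SE 0.06, adjusted p = 1.4e-07). Ifng, which encodes interferon gamma, was at 28.5 ± 5.11 against 0.113 ± 0.0377. Gzma was at 2.07 ± 1.45 and did not differ detectably from its 1.93 ± 0.17 in naive cells (adjusted p = 0.965). In all, 3854 genes were higher and 2602 lower, of which 558 and 274 by at least 2-fold, and the median log2 fold change was 0.07. This excess of higher genes depended on the scaling, since 59.7% of the calls were higher as deposited, 53.5% after upper-quartile scaling and 46.6% after quantile normalization.

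Other largest rises in memory cells included those of S100a4 (83.9 ± 4.1 FPKM), S100a6 (3.07 ± 0.823 to 149.7 ± 0.651), Ctla2a (0.835 ± 0.159 to 43.5 ± 2.4), Plek (0.0827 ± 0.0266 to 22.9 ± 0.864) and Itgb1 (5.14 ± 0.569 to 128 ± 2.49). The integrin beta 1 gene Itgb1 was at about the level of effector cells, and memory against effector did not pass the test (adjusted p = 0.116). The largest falls included Igfbp4, Dapl1, Itgae and Ccr9, which were at 0.471 ± 0.141, 0.659 ± 0.0434, 0.293 ± 0.0675 and 0.383 ± 0.0781 FPKM. Atp1b1, a sodium pump subunit, fell from 19.5 ± 2.05 to 0.474 ± 0.0864, the sialyltransferase gene St6gal1 from 17.6 ± 0.0479 to 0.546 ± 0.214, and the actin-severing gene Gsn from 14.1 ± 0.506 to 0.562 ± 0.237. The clone-named gene AC073553.2, with 52.4% of its 50-base stretches in another gene, fell from 78.4 ± 1.33 to 7.48 ± 0.0952.

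Of the fixed lists, 17 of 18 cytotoxic genes were higher in memory than in naive cells and 0 lower (17 adjusted over the list alone, adjusted p = 6.21e-09, and adjusted p = 0.194 with an estimated correlation). All 15 killer-lectin and effector surface genes were higher (15 adjusted over the list alone, adjusted p = 4.77e-09, and adjusted p = 0.195 with an estimated correlation), led by Klrc1, from 0.0328 ± 0.013 to 19.5 ± 0.242 FPKM, and Itgax at 19.4 ± 1.58. Effector-associated transcription factor genes were higher in 11 and lower in 2 of 14 (11 and 2 adjusted over the list alone, adjusted p = 0.000623, and adjusted p = 0.194 with an estimated correlation). Tbx21 was at 35.1 ± 1.96 and Id2 at 93.4 ± 6.18 against 9.0 ± 3.26 in naive cells, and Irf4 and Runx3 fell by 0.37 and 0.17. Naive and central memory surface genes were lower in 10 and higher in 5 of 17 (11 and 5 adjusted over the list alone, adjusted p = 0.00115, and adjusted p = 0.216 with an estimated correlation). Among those that rose were Cxcr3, to 65.9 ± 2.03, and the sort marker Il7r. Naive and memory-associated transcription factor genes were lower in 10 and higher in 4 of 18 (12 and 4 adjusted over the list alone, adjusted p = 0.00231, and adjusted p = 0.224 with an estimated correlation). Id3 was at 1.42 ± 0.335 and Lef1 at 22.3 ± 1.88 against 71.9 ± 5.73 in naive cells, while Eomes rose to 16.1 ± 0.696 and Ets1 by 0.29 on the log2 scale.

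Neither list of cell division genes passed the test in memory against naive cells. Of 18 mitosis genes 5 were higher and 1 lower (3 and 0 adjusted over the list alone, adjusted p = 0.114), with Mki67 and Top2a up by 0.73 and 0.64, Cdc20 decreased by 0.32, and a median of 0.19 that turned to -0.04 under quantile normalization, where 2 were higher and 1 lower. DNA replication genes were higher in 11 and lower in 2 of 20 (11 and 2 adjusted over the list alone, adjusted p = 0.0832). Tk1 and Pola1 rose by 0.98 and 0.73, and Cdt1 and Mcm3 fell by 0.46 and 0.25. Of 15 cell cycle inhibitor and quiescence genes 9 were higher and 0 lower (9 adjusted over the list alone, adjusted p = 0.0195, and adjusted p = 0.398 with an estimated correlation), led by Rbl2 (8.47 ± 0.64 to 19.4 ± 0.576 FPKM) and Slfn2. The count depended on the scaling, with 8 higher and 1 lower after upper-quartile scaling and 9 and 3 after quantile normalization. Apoptosis regulators were higher in 8 and lower in 3 of 18 (8 and 3 adjusted over the list alone, adjusted p = 0.332). Bcl2 rose to 33.8 ± 1.5 from 10.6 ± 1.34 in naive cells, and Bcl2a1b rose by 2.24, while Bmf and Casp8 fell by 0.67 and 0.35.

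Interferon-stimulated genes were lower in 17 and higher in 1 of 21 (17 and 1 adjusted over the list alone, adjusted p = 2.14e-08, and adjusted p = 0.211 with an estimated correlation), with Oas2 at 0.301 ± 0.0503 and Ifit1 at 1.27 ± 0.242 FPKM and Oas1a up by 0.50. Chromatin regulators were lower in 13 and higher in 5 of 22 (13 and 5 adjusted over the list alone, adjusted p = 0.00308, and adjusted p = 0.211 with an estimated correlation), and 13 lower and 2 higher after either other scaling. The demethylase gene Kdm6b went from 19.9 ± 1.11 to 6.07 ± 0.42 and the de novo DNA methyltransferase gene Dnmt3a from 8.26 ± 0.444 to 3.17 ± 0.124, and Ezh1 and Ezh2 rose by 0.45 and 0.38. Immediate early genes were lower in 9 and higher in 1 of 14 (9 and 1 adjusted over the list alone, adjusted p = 0.000523, and adjusted p = 0.414 with an estimated correlation). Nr4a1 and Egr1 fell by 1.64 and 1.49, and Fosb rose by 2.05. Chemokine receptor, integrin and homing genes were higher in 12 and lower in 1 of 15 (12 and 1 adjusted over the list alone, adjusted p = 7.61e-06, and adjusted p = 0.194 with an estimated correlation). Cd69 fell by 0.74. Inhibitory receptor genes were higher in 7 and lower in 1 of 10 (8 and 1 adjusted over the list alone, adjusted p = 0.0142, and adjusted p = 0.216 with an estimated correlation), with Tigit at 6.25 ± 0.0805, Lilrb4 at 1.83 ± 0.308 and Tox decreased by 1.17. Cytokine receptor genes were higher in 9 and lower in 7 of 20 (9 and 7 adjusted over the list alone, adjusted p = 0.943, and a median of 0.02 that turned to -0.03 under upper-quartile scaling). Il18rap and Il18r1 rose by 4.13 and 3.96, and Ifngr2 and Il21r fell by 2.56 and 1.40.

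Among the remaining lists, the NK cell list passed the test in memory against naive cells and the others missed the threshold. Glycolysis genes were higher in 6 and lower in 4 of 15 (7 and 4 adjusted over the list alone, adjusted p = 0.405). Pfkp and Hk2 rose by 1.04 and 0.97, and Hk1 and Gapdh, whose values are uncertain, fell by 0.36 and 0.35. Oxidative phosphorylation genes were higher in 7 and lower in 3 of 23 (4 and 3 adjusted over the list alone, adjusted p = 0.731). The counts became 4 and 4 after upper-quartile scaling and 5 and 4 after quantile normalization. Atp5c1 rose by 0.41, and Cyc1 fell by 0.29. Fatty acid oxidation genes were higher in 5 and lower in 4 of 16 (5 and 4 adjusted over the list alone, adjusted p = 0.692, and a median of 0.07 while the camera direction was down). This balance turned with the scaling, to 5 higher and 6 lower after upper-quartile scaling and 2 and 5 after quantile normalization. Acadl rose by 0.60, and Lipa and Cpt1a fell by 0.76 and 0.63. Ribosomal protein genes were higher in 4 and lower in 4 of 20 (4 and 4 adjusted over the list alone, adjusted p = 0.179). The counts were 3 and 7 after upper-quartile scaling and 3 and 6 after quantile normalization. Rps16 rose by 0.31, and Rpl8 and Rplp0 fell by 0.37 and 0.32. CD8 T cell identity genes were higher in 1 and lower in 4 of 12 (1 and 4 adjusted over the list alone, adjusted p = 0.153). Cd2 rose by 0.38, and Cd5 and Lat fell by 0.67 and 0.61. Of the markers of other cell types, 5 of 8 myeloid genes were higher and 0 lower (5 adjusted over the list alone, adjusted p = 0.157, and 3 higher after quantile normalization), with Mpeg1 at 1.49 and 3.02 and Csf1r at 2.56 and 5.44 FPKM in memory replicates 1 and 2. B cell genes were higher in 4 and lower in 1 of 6 (5 and 1 adjusted over the list alone, adjusted p = 0.199), with Cd74 at 9.22 and 18.2 in memory replicates 1 and 2 and Cd79b decreased by 1.11. All 3 tested NK cell genes were higher (3 adjusted over the list alone, adjusted p = 0.0221, and adjusted p = 0.231 with an estimated correlation), while the untested Ncr1 had 0 reads in both memory libraries. Klrb1f rose by 1.46. CD4 T cell genes were higher in 3 and lower in 1 of 4 (3 and 1 adjusted over the list alone, adjusted p = 0.261), with Zbtb7b at 7.55 ± 0.496, and of 3 erythroid genes 0 were called (0 adjusted over the list alone, adjusted p = 0.765).

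With 1 library left out, several small calls of memory against naive cells were lost. Cdc20 was lost without any single library other than memory replicate 2 (adjusted p = 0.0892 to 0.198) and Gapdh without any other than memory replicate 1 (adjusted p = 0.0575 to 0.12). Mcm3 and Ezh2 were lost without naive replicate 1 or 2 or memory replicate 2 (adjusted p = 0.0543 to 0.132 and 0.0503 to 0.115), and Runx3 without naive replicate 2 or either memory library (adjusted p = 0.0923 to 0.178). Irf4 was lost without naive replicate 1 or memory replicate 2 (adjusted p = 0.0733 to 0.105) and Rps16 without naive replicate 2 or memory replicate 2 (adjusted p = 0.0651 to 0.066). Cyc1 and Csf1r were lost without either naive library (adjusted p = 0.0754 to 0.0848 and 0.0691 to 0.0746). Oas1a was lost without naive replicate 1 (adjusted p = 0.0851) and Atp5b without memory replicate 1 (adjusted p = 0.0591). Ndufb5 was lost without either naive library or memory replicate 2 (adjusted p = 0.136 to 0.176).

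Effector and memory cells were then set side by side against the same naive libraries. They shared 3817 genes called in the same direction, 1990 higher and 1827 lower, and 875 called in opposite directions. Of the 926 genes at least 2-fold higher in effector cells, 755 were lower in memory than in effector cells and 652 were also called higher than in naive cells, among them Ccl5, Tbx21 and Cx3cr1. Of the 937 at least 2-fold lower, 775 were higher in memory than in effector cells and 578 were also called lower than in naive cells, among them Tcf7 and Ccr7. Independent lists of these sizes would share 1139 higher and 960.5 lower genes. Unchanged stages simulated 100 times against shared naive libraries shared a mean of 0.03 genes, with a mean of 0.23 called in effector against naive. So few calls leave almost nothing to share, so this count says nothing about overlap at the observed numbers of calls. The covariance of the log2 fold changes was 0.33, against 0.01 in the simulations, and their correlation across genes was 0.62 against 0.50. The log2 fold changes had the same sign in 65.1% of genes, against 66.7% in the simulations. No gene differed in those simulations, so their correlation and share of equal signs came only from noise of the shared naive libraries. With the larger covariance in the data, these 2 simulated values are no baseline for it. In an alternative chosen after seeing the data, each stage was set against a different naive library, which was assumed to vary like the other stages. With no naive library in common, the covariance was 0.33 and 0.32 for the 2 ways of pairing, and the same sign was found in 66.0% and 62.8% of genes. Shared calls were 1512 and 1527 higher, against 718 and 805 for independent lists, and 1337 and 1385 lower, against 593 and 662.

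**Figure D3:**
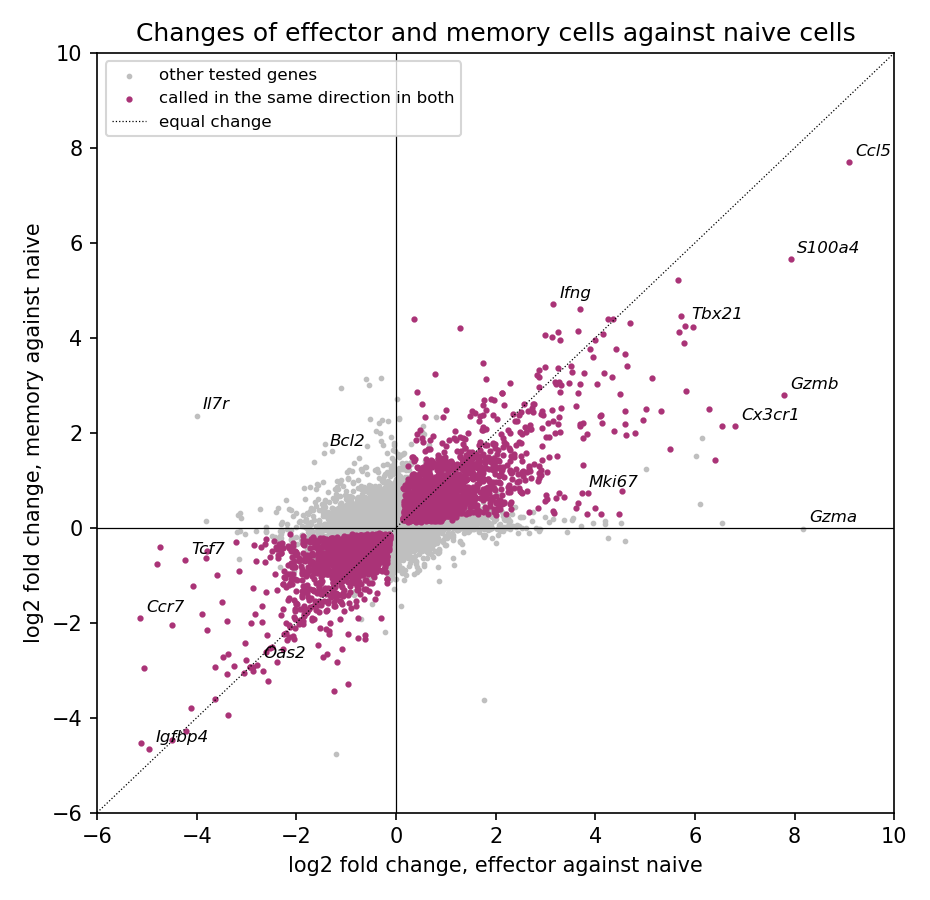
Log2 fold change of each of 11977 tested genes in effector (horizontal) and memory (vertical) against naive cells, with the 3817 genes called in the same direction in both in purple and a dotted line of equal change. Ccl5 and S100a4 lay far from 0 on both axes, whereas Gzma, at 8.17 and -0.02, was higher in effector cells alone.

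The comparison of memory with effector cells asked directly how the stages after infection differed. Memory cells had more transcripts of Tcf7, Ccr7, Bcl2 and the sort marker Il7r, and fewer of Gzma, Gzmb, Cx3cr1 and cell division genes. Tcf7 was at 169 ± 1.08 against 13.5 ± 0.282 FPKM (log2 fold change 3.55, SE 0.04, adjusted p = 4.5e-07), Ccr7 at 18.1 ± 0.867 against 1.03 ± 0.277, and Bcl2 at 33.8 ± 1.5 against 3.23 ± 0.0188. Gzma was at 2.07 ± 1.45 against 842 ± 27.9 (log2 fold change -8.19, SE 0.29, adjusted p = 1.04e-05) and Gzmb at 8.53 ± 1.52 against 304 ± 27.3. In all, 4952 genes were higher and 2930 lower in memory cells, of which 797 and 489 by at least 2-fold. The median log2 fold change was 0.13 as deposited and 0.0017 after quantile normalization, which shifted single genes by a median of -0.14, and 62.8% of the calls were higher as deposited against 49.2% after that normalization and 57.5% after upper-quartile scaling. Differences of this size depend on the scaling.

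Further genes among the largest rises were Nsg2 (28.9 ± 2.16 FPKM against 0.478 ± 0.00393), Mid1 (21.6 ± 0.396 against 0.37 ± 0.0478), Prss12 (11.5 ± 0.985 against 0.0553 ± 0.0258) and the clone-named AC124005.1 (37.5 ± 5.87 against 1.47 ± 0.543), all of whose 50-base stretches occurred in another gene. Prss12 and Mid1 were also higher than in naive cells, by 3.02 and 2.95 on the log2 scale. Among the largest falls were Cx3cr1, to 3.78 ± 0.468 from 121 ± 2.04, Klrg1, the integrin gene Itgam, to 0.324 ± 0.0346 from 23.3 ± 1.17, and the clone-named AL929120.1, to 2.15 ± 0.274 from 44.0 ± 1.89. Most of the sequence of Itgam (72.4% of its 50-base stretches) was shared with other annotated genes. S100a9 and S100a8, which are neutrophil genes, were also among them, at 39.8 ± 23.7 and 25.9 ± 14.6 in effector libraries, with effector replicate 1 the higher of the pair.

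Of the fixed lists, naive and central memory surface genes were higher in 15 and lower in 0 of 17 (15 adjusted over the list alone, adjusted p = 4.19e-05, and adjusted p = 0.204 with an estimated correlation). Effector-associated transcription factor genes were lower in 11 and higher in 1 of 14 (12 and 1 adjusted over the list alone, adjusted p = 1.04e-05, and adjusted p = 0.194 with an estimated correlation). Zeb2 fell to 1.62 ± 0.129 from 13.03 ± 0.373 FPKM and Bhlhe40 to 10.5 ± 1.24 from 44.6 ± 2.37, and Stat4 rose by 0.54. Mitosis genes were lower in 18 of 18 (18 adjusted over the list alone, adjusted p = 2.06e-12, and adjusted p = 0.194 with an estimated correlation) and DNA replication genes in 16 of 20, with 0 higher (16 adjusted over the list alone, adjusted p = 7.84e-07, and adjusted p = 0.239 with an estimated correlation). Ube2c and Mki67 fell by 3.18 and 3.01, and Rrm2 and Chaf1a by 2.58 and 1.56. Cytotoxic genes were lower in 9 and higher in 4 of 18 (10 and 4 adjusted over the list alone, adjusted p = 0.00366, which became 0.0579 under quantile normalization, and adjusted p = 0.262 with an estimated correlation). Those higher included Gzmm, at 14.6 ± 3.45 against 3.66 ± 0.0715, and Ifng, at 28.5 ± 5.11 against 8.97 ± 1.17. Killer-lectin and effector surface genes were lower in 8 and higher in 5 of 15 (8 and 5 adjusted over the list alone, adjusted p = 0.0108, which became 0.0596 under quantile normalization, and adjusted p = 0.35 with an estimated correlation). After quantile normalization 8 were lower and 3 higher. Cd44 and Klrk1 rose by 0.88 and 0.87.

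Ribosomal protein genes were higher in 18 and lower in 0 of 20 (18 adjusted over the list alone, adjusted p = 4.75e-06, and adjusted p = 0.211 with an estimated correlation), with Rps16 at 167 ± 12.7 against 54.3 ± 0.011 FPKM and Rps19 at 39.3 ± 0.557 against 14.9 ± 0.0809. Glycolysis genes were lower in 9 and higher in 2 of 15 (9 and 2 adjusted over the list alone, adjusted p = 0.00141, and adjusted p = 0.224 with an estimated correlation). Slc2a3 and Hk2 fell by 0.98 each, and Gapdh and Slc2a1 rose by 0.92 and 0.36, with the values of Gapdh uncertain. Oxidative phosphorylation genes were lower in 13 and higher in 2 of 23 (13 and 2 adjusted over the list alone, adjusted p = 0.0122, which became 0.136 under quantile normalization, and adjusted p = 0.216 with an estimated correlation). Only 8 were lower and 1 higher after quantile normalization. Cox5b fell by 0.76, and Sdha rose by 0.41. Fatty acid oxidation genes were lower in 7 and higher in 2 of 16 (6 and 2 adjusted over the list alone, adjusted p = 0.0328, and adjusted p = 0.47 with an estimated correlation). The 2 higher genes were Hadhb, with 62.4% shared stretches, and Acadm, up by 0.46 and 0.24, and Cpt1a, the gateway of fatty acids into mitochondria, fell to 6.98 ± 0.0542 from 14.2 ± 0.79. Interferon-stimulated genes were lower in 7 and higher in 2 of 21 (7 and 2 adjusted over the list alone, adjusted p = 0.0328, and adjusted p = 0.461 with an estimated correlation), with 11 lower and 2 higher after quantile normalization. Irf9 fell by 0.73, and Usp18 and Oas3 rose by 1.17 and 0.55. Apoptosis regulators were lower in 8 and higher in 5 of 18 (8 and 5 adjusted over the list alone, adjusted p = 0.0451, which became 0.0949 under quantile normalization, and adjusted p = 0.239 with an estimated correlation). The counts were 9 lower and 3 higher after upper-quartile scaling and 10 and 2 after quantile normalization. Bak1 fell by 1.24, and Bbc3 rose by 0.45. CD8 T cell identity genes were lower in 6 and higher in 2 of 12 (6 and 2 adjusted over the list alone, adjusted p = 0.0118, which became 0.183 under quantile normalization, and adjusted p = 0.279 with an estimated correlation). After upper-quartile scaling 10 were lower and 1 higher. Cd247 and Zap70 fell by 0.54 and 0.44, and Cd3g rose by 0.21.

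Over members with under 10% of their 50-base stretches in another gene, a test chosen after seeing the data, 4 of these lists missed the threshold in memory against effector cells. Their adjusted p was then 0.099 for killer-lectin and effector surface genes and 0.0603 for glycolysis genes. It was 0.16 for interferon-stimulated genes and 0.0667 for apoptosis regulators.

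Several lists missed the threshold in memory against effector cells. Naive and memory-associated transcription factor genes were higher in 9 and lower in 6 of 18 (10 and 6 adjusted over the list alone, adjusted p = 0.497), with Bach2 at 3.97 ± 0.59 against 0.958 ± 0.0587 FPKM and Runx1 and Klf2 decreased by 0.89 and 0.67. Chemokine receptor, integrin and homing genes were higher in 6 and lower in 5 of 15 (6 and 5 adjusted over the list alone, adjusted p = 0.502), with Gpr183 at 19.3 ± 0.538 against 2.46 ± 0.295 and Itgb2 and Itgal decreased by 1.29 and 1.09. Inhibitory receptor genes were higher in 4 and lower in 6 of 10 (4 and 6 adjusted over the list alone, adjusted p = 0.0839). Havcr2 and Lag3 fell by 3.21 and 2.79, and Btla and Cd101 rose by 1.45 and 1.16. Cytokine receptor and signalling genes were higher in 8 and lower in 4 of 20 (8 and 4 adjusted over the list alone, adjusted p = 0.694). Socs1 and Socs3 rose by 1.92 and 1.90. Cell cycle inhibitor genes were higher in 7 and lower in 5 of 15 (7 and 5 adjusted over the list alone, adjusted p = 0.869), with 5 and 5 after upper-quartile scaling and 6 and 6 after quantile normalization. Btg1 and Cdkn1b rose by 1.19 and 0.53. Chromatin regulators were higher in 7 and lower in 8 of 22 (7 and 8 adjusted over the list alone, adjusted p = 0.179). Uhrf1 fell by 1.51, and Hdac7 rose by 0.36. Immediate early genes were higher in 6 and lower in 4 of 14 (6 and 4 adjusted over the list alone, adjusted p = 0.68), with Jun at 22.2 ± 0.797 against 3.83 ± 0.452 and Nr4a1 and Atf3 decreased by 1.74 and 1.55. For the homing and the cell cycle inhibitor lists the medians were 0.04 and 0.17 while the camera direction was down, and the former turned to -0.02 under upper-quartile scaling.

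With 1 library left out, 4 of the genes named in memory against effector cells lost their call. Slc2a1 was lost without either effector library (adjusted p = 0.051 to 0.0657), Acadm without effector replicate 2 or memory replicate 2 (adjusted p = 0.0669 to 0.111), and Cd3g and Ndufs1 without any single effector or memory library (adjusted p = 0.0597 to 0.0909 and 0.0526 to 0.149).

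B cell, myeloid and erythroid genes were mostly lower in memory than in effector libraries, whereas Pecam1 was higher. All 6 B cell genes (6 adjusted over the list alone, adjusted p = 0.000567, and adjusted p = 0.226 with an estimated correlation) and 7 of 8 myeloid genes with 0 higher (7 adjusted over the list alone, adjusted p = 0.000875, and adjusted p = 0.367 with an estimated correlation) were lower, with Lyz2 at 1.01 ± 0.254 FPKM against 26.6 ± 6.16. Csf1r did not pass the test, at 4.00 ± 2.04 against 3.04 ± 0.431. Pecam1 was at 8.92 ± 0.312 against 4.76 ± 0.328 (log2 fold change 0.79, adjusted p = 0.000118). All 3 erythroid genes were lower (3 adjusted over the list alone, adjusted p = 0.0653). CD4 T cell genes were higher in 2 and lower in 1 of 4 (2 and 2 adjusted over the list alone, adjusted p = 0.694, and a median of 0.11 that turned to -0.10 under quantile normalization), with Ctla4 up by 0.56, and of 3 NK cell genes 1 was higher and 1 lower (1 and 1 adjusted over the list alone, adjusted p = 0.522). Effector replicate 1 exceeded replicate 2 in all 8 tested myeloid genes. The T cell receptor genes Trac and Trbc1, and the genes Igkc and Hmox1, fell outside the rule for named genes. They were chosen after their values were seen and are plotted with these markers. Ighm was also chosen after its values were seen.

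**Figure D4:**
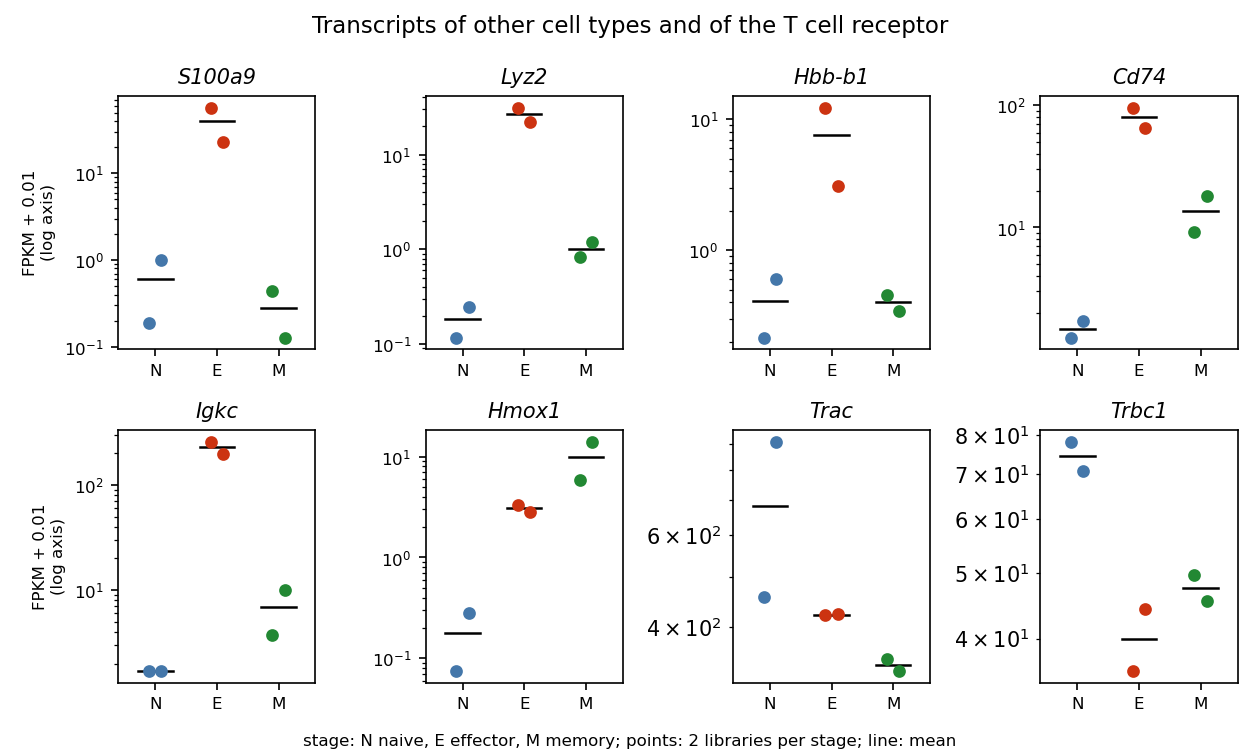
FPKM (log axis, with 0.01 added) of 6 transcripts of other cell types and of the T cell receptor genes Trac and Trbc1 in naive, effector and memory libraries, as 1 point per library with a line at the mean. S100a9 was at 56.6 and 23.1 in the 2 effector libraries, and Trac at 457 and 907.6 in the 2 naive libraries, where Trbc1 was at 78.2 and 70.8.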

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

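The tests with limma-voom, with other choices of transcript, with split naive libraries and with genes of under 10% shared 50-base stretches were chosen after the results had been seen. Counts of called genes stayed within 1.5 times their reported values except as follows. With a minimum of 5 FPKM, where fewer genes were tested, 2283 genes were higher and 2593 lower in effector than in naive cells, 2216 were higher in memory than in naive and 2588 higher in memory than in effector cells. At an adjusted p under 0.01, 2543 genes were higher and 1731 lower in memory than in naive cells. With a 2-fold minimum, the counts were 926 higher and 937 lower (effector against naive), 558 and 274 (memory against naive), and 797 and 489 (memory against effector), and 544 genes were shared in direction by both stages against naive cells. Of the 44 list tests passed with the preset correlation, 0 passed with an estimated correlation, while fry passed 65, quantile normalization 37 and the restriction to members with under 10% shared stretches 37. Leaving out each library in turn, where the lone library of a stage is assumed to vary like the others, gave 2901 to 3663 higher and 3582 to 4584 lower genes for effector against naive. It gave 2702 to 3456 and 1891 to 2432 for memory against naive, 3833 to 4791 and 2280 to 2863 for memory against effector, and 2789 to 3598 shared genes. The list tests were not repeated without single libraries.

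Across all genes, some calls turned to the opposite direction, for a cause not tested. For effector against naive, memory against naive and memory against effector these were 7, 20 and 12 genes with the transcript of highest mean FPKM and 3, 1 and 2 with the mean over transcripts, and 1 gene in effector against naive under quantile normalization. Among the lists and named genes, directions that reversed belonged to results that had not passed their tests, and the cause was not tested. Under quantile normalization these were the cytokine receptor list in effector against naive cells (adjusted p = 0.864) and, in memory against effector cells, the cell cycle inhibitor (adjusted p = 0.864) and chemokine receptor lists (adjusted p = 0.965). With fry they were the cytokine receptor list in effector against naive (adjusted p = 0.0765), the fatty acid list in memory against naive (adjusted p = 0.867) and the cell cycle inhibitor list in memory against effector cells (adjusted p = 0.539). The log2 fold change of Cd8a became -0.0427 (effector against naive), -0.00473 (memory against naive) and 0.038 (memory against effector) under quantile normalization. In memory against naive cells it was -0.0159 with upper-quartile scaling and -0.0189 with limma-voom. Over 277 comparisons of named genes and 22 alternatives, 5777 values kept their direction and side of the threshold, 220 lost the call, 2 gained it and 5 reversed, and 22 of these comparisons lost the call without at least 1 library.

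The replicate numbers did not pair the libraries, with correlations of the replicate differences of -0.09, 0.01 and -0.02 between stages across genes. A fit with the replicate block called 3443 and 4308 genes for effector against naive, 3637 and 2453 for memory against naive, 4783 and 2808 for memory against effector, 3586 shared genes and 44 list tests. Depth limited the memory libraries most, at 698 and 774 reads for the median tested gene.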

Other observations

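The tests below were chosen after the results had been seen, except that of ribosomal protein genes outside the fixed list, and the genes named here were chosen after their values were seen. All 8 tested protein-coding genes of the mitochondrial genome were higher in memory than in naive cells (median log2 fold change 0.92) and than in effector cells (median 1.38), and 7 were lower in effector than in naive cells (median -0.40). The complex I gene mt-Nd2 was at 214 and 227 FPKM in the naive, 101 and 101 in the effector and 438 and 409 in the memory libraries, and mt-Co1 at 569.6 and 597, 521 and 502, and 995 and 999 FPKM. The log2 fold changes of all 8 stayed positive in memory against naive and against effector cells under both other scalings, but the change of mt-Cytb in memory against naive cells went from 0.27 to 0.07 under quantile normalization. The shares of 50-base stretches in another gene were 98.0% for mt-Nd3, which had at most 4 reads in a naive or effector library, 62.2% for mt-Nd4 and 51.1% for mt-Co1, so their values are uncertain. The mitochondrial ribosomal RNAs differed from this. In the naive, effector and memory libraries mt-Rnr1 had means of 77.7, 165 and 99.98 FPKM and was called lower in memory than in effector cells (log2 fold change -0.71). The means of mt-Rnr2 were 91.4, 96.6 and 196, and it was called higher in memory cells than at both other stages.

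Markers of macrophages of the spleen differed between the memory libraries. Hmox1 was at 5.83 and 14.0 FPKM and Vcam1 at 2.75 and 6.6 in memory replicates 1 and 2, and C1qa at 3.5 and 7.35. In both effector libraries these genes were lower, with Hmox1 at 3.28 and 2.82, Vcam1 at 0.989 and 0.721 and C1qa at 3.23 and 2.44, and memory against effector was called for Hmox1 and Vcam1 but not C1qa (adjusted p = 0.0685). The median log2 ratio of memory replicate 2 to 1 was 0.63 over the B cell list and 0.15 over the myeloid list, at percentiles 100 and 98.2 among 10000 random lists of the same size matched on mean expression, which describes these libraries only.

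Transcripts of other cell types in the effector libraries may come from other cells or their RNA in the sort, in unequal amounts. The median log2 ratio of effector replicate 1 to 2 was 0.521 over the myeloid list, with 8 of 8 genes higher, S100a9 at 56.6 and 23.1 FPKM and Lyz2 at 31.0 and 22.2, and 0.307 over the B cell list, with 4 of 6 genes higher, Cd74 at 95.3 and 65.4 and Igkc at 257 and 199, while Ighm was at 43.4 and 41.0. Both medians lay at percentile 100 among 10000 random lists of the same size matched on mean expression, which describes these libraries only. The median of 0.00887 over all tested genes argues against scaling or depth. These medians cannot tell other cells from T cells that differed between the libraries, since both would raise these lists. The neutrophil genes S100a8, S100a9, Ngp and Ltf had similar ratios of effector replicate 1 to 2, at 2.32, 2.45, 2.35 and 2.34. Those of Cd3d, Cd3e, Cd3g and Cd247 were 0.97, 0.958, 0.974 and 0.966. Unequal amounts of neutrophil RNA would give 1 common ratio in such genes, but this was not tested, and Lyz2 was at 1.39. A change in the T cells by stage stays open, although the gate on CD8 and KLRG1 should remove other cells.

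Ribosomal protein transcripts were lower in effector cells, with 67 of 69 tested Rps and Rpl genes called lower. The 6 genes outside the list with under 10% shared 50-base stretches were all called lower, with a median log2 fold change of -0.995. For these 6 genes this argues against reads shared through exact stretches of other annotated transcripts. The measure does not cover diverged or unannotated pseudogenes, so sharing with those stays open. The list median of -0.986 under quantile normalization argues against scaling. The larger share of reads in the 10 most abundant genes (5.47% against 4.58%) would force a change of only -0.0135 on the log2 scale. A lower level of these transcripts at the effector stage is a hypothesis that remains, with tissue, time and sort untested.

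Trac was at 457 and 907.6 FPKM, Trbc2 at 219.7 and 324 and Trbv13-3 at 107 and 199.5 in naive replicates 1 and 2, whereas Trbc1 was at 78.2 and 70.8, and 22 of 37 tested receptor segment genes were higher in replicate 2. The shares of 50-base stretches in another gene were 61.1% for Trbc1 and 44.0% for Trbc2, so the values of these 2 genes are uncertain. Of 11977 tested genes, 17 had a ratio at least as high as that of Trac. The median log2 ratio of all tested genes, 0.0166, argues against scaling or depth, and that of the CD3 genes and Cd247, -0.0144 with a highest ratio of 0.15, against more of the whole receptor complex. Antigen-experienced cells would not raise Trac, since its highest level in an effector or memory library was 422.7. Unequal transgene dose between the cells of both libraries may be an explanation and was not tested.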
